A study of Mnemiopsis leidyi with 31 samples.

How the data were processed

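Embryos of the ctenophore (comb jelly) Mnemiopsis leidyi were sampled at 9 times, each hour from 1 to 9 hours post fertilization (hpf), and 31 RNA-seq libraries were deposited. Per the labels' protocols, total RNA was taken with Trizol from pools of 100 to 200 whole embryos of animals caught in the wild, polyadenylated RNA was selected on magnetic beads, and libraries were made with the ScriptSeq V2 kit with a shortened fragmentation, 15 PCR rounds and a size selection of 350 to 600 base pairs before Illumina sequencing. The series describes the libraries of an hour as biological replicates, and no label says which of them came from the same spawning. Every library has a code that starts with 2012 or 2013, and each of the 9 hours has libraries of both years, 12 with codes of 2012 and 19 with codes of 2013. At 3 hpf, the title and the description of 1 library give different codes, and the description, which also names its column, was used.

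The deposited count table held whole-number read counts of 31067 transcript records with a length in bases, from 300 to 29348 and with a median of 1078. The authors' alignment tools were Bowtie2 and SAMtools, per the submitters' processing notes, which give neither version nor role. The reference the reads were aligned to and the way reads were counted are not given in the sources used here, so how reads shared by near-identical records were divided is unknown, and counts of closely related records are uncertain. The records carry numbered identifiers with no names. None of them, 0 of 31067, was found in the gene name table used here, which belongs to another annotation (assembly crg_Mlei_v2). The gene lists fixed before the data were examined (transcription factors, cilia, histones, signalling and others) therefore could not be applied and no gene list test was run. Transcripts are named by identifier only, at most 2 that rose and 2 that fell per comparison.

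The deposited RPKM table was compared with the counts. For all 717940 values above 0, the total implied by the RPKM value rounded to 1413671828, which is the sum of the counts of all 31 libraries. The authors' RPKM values thus carried the length correction and 1 common total, and did not correct for the depth of each library. They were used only as an alternative, on the log2(RPKM + 1) and log2(RPKM + 0.1) scales, for records above 1 RPKM in at least 2 libraries. RPKM with each library's own total was computed from the counts as a further alternative.

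Total counts per library ran from 17608264 to 116632427. CPM stands for counts scaled to the library. For named transcripts, hours of the highest mean and the bins of the length test the library's total was multiplied by its TMM factor, and elsewhere the total alone was used. The factors of named transcripts came from the 19 libraries of 2013 for comparisons within that year, and from all 31 libraries otherwise and for values of single libraries that lay apart. RPKM stands for the count scaled by the length of the record and a total. Libraries had no molecular identifiers, so that intervals computed from counts cover counting error only. Columns were compared in pairs before use. Counts of 1 hpf 2012_N7 were below those of 9 hpf 2012_37 in 0 of 31067 records, and counts of 4 hpf 2012_N4 were below those of 5 hpf 2012_14 in 0 records. Every other pair had at least 253 records below. The deposited columns were kept as they were for the tests fixed before the data were examined. Alternatives chosen after seeing the data subtracted the smaller column from the larger, left out both larger columns, or left out both and 2 hpf 2012_N6.

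Tests were run in R 4.3.3 with edgeR 4.0.16. Records were filtered with filterByExpr with the hour as group, which left 23140, and normalized with TMM factors. The quasi-likelihood test was fitted with the hour as a factor with 9 levels over all 31 libraries. Contrasts were each hour against the hour before (8 steps) and 8 hpf against 1 hpf, and an F test covered all hours. A further fit added the code year as a term. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test with a threshold of 0.05 unless another tool is named. Standard errors (SE) of log2 fold changes were approximated as the absolute log2 fold change divided by the square root of the F statistic. The common biological coefficient of variation of this fit was 0.8785. The same fit on the 19 libraries with codes of 2013 (21255 records tested, coefficient 0.7075) was planned as an alternative. A test of a slope of log2 expression over the hours in these 19 libraries, again with edgeR's quasi-likelihood test, was added after seeing the data. It treats the libraries as independent, and the labels do not say whether libraries with like codes came from 1 spawning. P-values measure the spread between these libraries only.

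The rule for named transcripts was fixed before the data were examined. It took records past the threshold with a mean of at least 10 CPM at either hour and no overlap of log2 CPM (prior count 2) between the libraries of 1 and 8 hpf, ranked by fold change. It allowed more names, and was limited to 2 per direction because the records carry no names. For the F test it took records among the 5 smallest p-values. The same rule was carried over to the libraries with codes of 2013. Mle_005005, the most abundant transcript, lies outside this rule and was chosen after its values were seen. Principal components were computed on log2(CPM + 1) of records with a mean of at least 1 CPM. Correlations with the hour were computed separately in each code year, 4 in all, with two-sided permutation p-values from 100000 resamples.

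The fitting functions were tested on simulated data with counts drawn at the real means and library sizes and 200 records changed. Dispersions were those of the fitted trend, with no further spread of single records. The changed records were drawn from those with a mean of at least 10 CPM. Libraries were drawn independently, without likeness within code series, overlapping columns or libraries that lay apart. The shares recovered and the false calls hold for such data only. For 1 against 8 hpf with all 31 libraries, 36% of 4-fold changes and 98% of 16-fold changes were recovered among 21839 records, with 6 unchanged records called. With the 19 libraries of 2013, 32% and 92% were recovered among 19126 records, with 3 called. For the slopes, 64% of changes of 0.25 per hour and 100% of changes of 0.5 per hour were recovered among 19073 records, with 1 unchanged record called.

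Alternatives planned before the data were examined were RLE factors, library totals alone, no filter, the year as a term, the start of the code (year and next character) as a replicate block, DESeq2 1.42.0, limma 3.58.1 on the deposited RPKM, 1 code year alone, no 9 hpf libraries, only the hours compared, and leaving out in turn each library of the hours compared (of every hour for the F test and for code years). Leaving out each library of the other hours for 1 to 8 hpf was added after seeing the data. Calculations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.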

Results

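The series followed messenger RNA through the early embryo of Mnemiopsis leidyi, a comb jelly. The question was which transcripts change in level, and when, between early cleavage and the formation of the larval body. There were 3 libraries at 1 hpf, 4 at 2 hpf, 3 each at 3, 4 and 5 hpf, 4 each at 6 and 7 hpf, 5 at 8 hpf and 2 at 9 hpf, each from whole embryos. Total counts ran from 36175510 to 84494309 at 1 hpf and from 29195546 to 75651352 at 8 hpf, with the shallowest library at 5 hpf (17608264) and the deepest at 4 hpf (116632427). A single transcript, Mle_005005 (1573 bases), took the most counts in 28 of the 31 libraries, with 0.513% to 8.66% of each library. In 3 hpf 2013_23, the highest, the 95% Wilson interval was 8.645% to 8.669%. Its slope over the hours in the libraries of 2013 did not pass the threshold (-0.16 per hour on the log2 scale, adjusted p = 0.165, edgeR).

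Columns of the table overlapped in 2 cases. The 1 hpf library 2012_N7 was at or above the 9 hpf library 2012_37 in every one of the 29657 transcripts counted in the latter, whose total amounted to 83.69% of its own. After subtraction counts were left in 16062 transcripts. The 4 hpf library 2012_N4 stood in the same relation to the 5 hpf library 2012_14 over 23306 transcripts, with 68.8% of its total, and counts were left in 26706 transcripts. The next closest pair of columns had 253 transcripts the other way. Both larger columns count as replicates of their hour in the tests over all 31 libraries.

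The libraries with codes of 2013 shifted with the hour, though not in strict order. The first principal component, with 49.74% of the variance, rose with the hour across the 19 libraries of 2013 (Pearson r = 0.901, permutation p = 1e-05, the smallest that 100000 resamples can give; Benjamini-Hochberg adjusted p = 2e-05 over 4 relations; Spearman rho = 0.895, permutation p = 1e-05). Without the 2 libraries farthest from the median hour, of which 3 pairs were equally far, r was between 0.88 and 0.891. The number of transcripts at 1 CPM or more also rose, from 7888 in 2 hpf 2013_42 to 14174 in 8 hpf 2013_48 (r = 0.848, permutation p = 1e-05, adjusted p = 2e-05; rho = 0.896, permutation p = 1e-05; r between 0.796 and 0.824 without the 2 farthest). In the 12 libraries with codes of 2012 neither relation passed. There r was 0.256 for the component (permutation p = 0.418, adjusted p = 0.471; rho = 0.373, permutation p = 0.231) and 0.228 for the number of transcripts (permutation p = 0.471, adjusted p = 0.471; rho = 0.316, permutation p = 0.314). Farthest from the median hour was 1 hpf 2012_N7, and 2 hpf 2012_N6 and 9 hpf 2012_37 were equally far behind it. Without 2012_N7 and 2012_N6 these were 0.716 (permutation p = 0.0233) and 0.699 (permutation p = 0.028), and without 2012_N7 and 2012_37 they were 0.355 (permutation p = 0.307) and 0.291 (permutation p = 0.406).

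**Figure D1:**
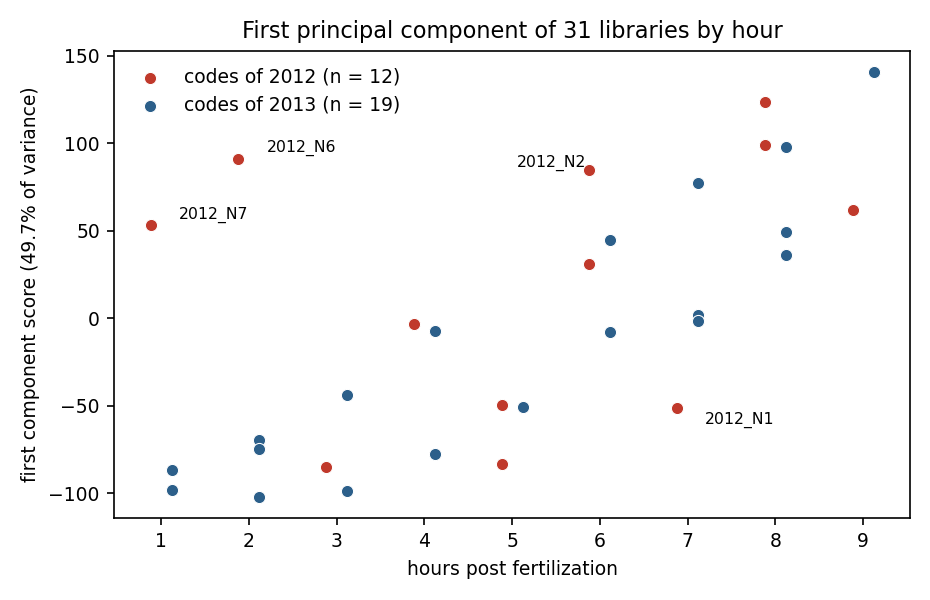
Score of each library on the first principal component (vertical axis, no unit) against hours post fertilization (horizontal axis), 1 point per library, with red for codes of 2012 and blue for codes of 2013 and small sideways shifts to separate the years. Libraries of 2013 lie between -102 and 141 and rise with the hour (r = 0.901), while 2012_N6 at 2 hpf lies at 91.2.

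From 1 to 8 hpf, as the columns were deposited, 1 of 23140 transcripts passed the threshold. Mle_011620 (4581 bases) fell from 76.5 ± 74.5 CPM at 1 hpf (SD, n = 3) to 11.5 ± 1.88 CPM at 8 hpf (SD, n = 5), a log2 fold change of -2.73 (SE 0.44, adjusted p = 0.0274, edgeR). Its 1 hpf values spread from 22.2 to 161 CPM, and it was lower in all 5 libraries of 8 hpf than in any of 1 hpf. An unadjusted p under 0.05 was seen for 2988 transcripts. The count turned on single columns. Without 1 hpf 2012_N7, 5688 transcripts passed (3826 higher and 1862 lower at 8 hpf), and after subtraction of the shared counts 8911 did (6727 higher, 2184 lower). Leaving out 2 hpf 2012_N6 alone, a library of neither hour that enters through the common spread, gave 1 higher and 595 lower. The call of Mle_011620 ended without 1 hpf 2013_41 or without any one of 8 hpf 2012_18, 2012_N8B, 2013_28 and 2013_48, with 0 calls each. Between 6 and 22 transcripts, all lower, passed without 3 hpf 2012_N5, 6 hpf 2012_N2, 7 hpf 2012_N1, 7 hpf 2013_47, 8 hpf 2013_18 or 9 hpf 2013_49. RLE factors, library totals alone and limma gave 0, and DESeq2 gave 28.

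Within the libraries of 2013, 2663 transcripts were higher and 464 lower at 8 hpf (n = 3) than at 1 hpf (n = 2), of 21255 tested. The largest rises under the rule were Mle_005806 (857 bases) and Mle_005099 (1640 bases), both with 0 counts in the 1 hpf libraries of 2013. Mle_005806 reached 37.8 ± 16.6 CPM at 8 hpf (SD, n = 3; adjusted p = 0.0373, edgeR). This mean was 849-fold the floor of 3 counts over both 1 hpf libraries (0.0446 CPM). Mle_005099 reached 12.2 ± 10.7 CPM (SD, n = 3; adjusted p = 0.0373, edgeR), a mean 273-fold that floor. Mle_010156 (1025 bases) fell from 60 ± 29.2 CPM (SD, n = 2) to 5.27 ± 1.39 CPM (SD, n = 3), a log2 fold change of -3.51 (SE 0.49, adjusted p = 0.0373, edgeR). Mle_005673, described with the slopes, fell by 3.15 on the log2 scale (SE 0.72, adjusted p = 0.0373, edgeR). These calls did not survive the loss of 1 library: without any one of the 2 libraries of 1 hpf or the 3 of 8 hpf edgeR called 0 transcripts, with between 4278 and 8563 at an unadjusted p under 0.05. Without 6 hpf 2013_26, 6 hpf 2013_46, 7 hpf 2013_17 or 7 hpf 2013_27 it called 145, 139, 1817 and 942, and without 2 hpf 2013_42 it called 5914. With all 19 libraries DESeq2 called 7211 and limma on RPKM per library 2831. In the libraries of 2012 edgeR called 0, with 340 at an unadjusted p under 0.05, but their only 1 hpf library is 2012_N7, which is nowhere below a 9 hpf column, so this 0 decides nothing.

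A slope over the hours, a test chosen after the results above were seen, used all 19 libraries of 2013. Of 21255 transcripts, 9643 rose and 3168 fell with the hour. The median slope of the rising ones was 0.60 per hour on the log2 scale (quartiles 0.47 and 0.76) and that of the falling ones -0.19 (quartiles -0.26 and -0.15). Counts of calls ran from 10802 to 13528 when each library was left out in turn, though without 8 hpf 2013_28 the falling ones numbered 1681. Scaling moved the split: RLE factors gave 10927 rising and 1854 falling, and library totals alone 10278 and 1715. The median slope of all transcripts, 0.20 with TMM factors, was higher by 0.07 under RLE factors and by 0.04 under library totals. Library totals, with the smaller shift, left fewer falling transcripts, and whether the shift moved the split was not tested. Of the 3168 falling transcripts, 1854 and 1715 also fell under RLE factors and under library totals, and none turned to a rise. The limma test on log2(RPKM per library + 1) called 4886 rising and 1656 falling. Without code series 2013_2, the 8 libraries whose codes start with 2013_2, 7223 rose and 649 fell, and without the 6 of code series 2013_4, 5277 rose and 3313 fell. Over all 31 libraries as deposited the balance turned, with 2527 rising and 3529 falling. After subtraction of the shared counts 5603 rose and 4174 fell there. The same slope test called 0 of 26689 transcripts in the 12 libraries of 2012. There 25 had an unadjusted p under 0.05, fewer than the share of 0.05 that chance alone would give. This 0 therefore does not show that levels stayed the same, and no other tool was run there. A term for the difference in slope between years passed for 1668 of 23140 transcripts, 1637 of them with the higher slope in 2013, and for 252 of 22878 after subtraction of the shared counts. These results take the hours of the 2012 codes as labelled, although 2 hpf 2012_N6 and 7 hpf 2012_N1 lie apart from the other libraries of their hours.

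The 2 steepest rises under the rule had means under 1 CPM at each hour up to 5 hpf in the libraries of 2013. Mle_016409 (3263 bases) had 3 counts over both 1 hpf libraries of 2013 and 0.0438 ± 0.0171 CPM there (SD, n = 2). It stood at 1.07 ± 1.42 CPM at 6 hpf (SD, n = 2), 13 ± 11.3 CPM at 7 hpf (SD, n = 3) and 26.1 ± 17.6 CPM at 8 hpf (SD, n = 3). Its slope was 1.77 per hour (SE 0.17, adjusted p = 3.83e-07, edgeR), and its pooled counts, scaled by the same library sizes, rose 635-fold from 1 to 8 hpf (95% counting interval 217 to 3080). Mle_016764 (603 bases) had 2 counts at 1 hpf, 17.4 ± 11.2 CPM at 7 hpf (SD, n = 3) and 62.4 ± 23.5 CPM at 8 hpf (SD, n = 3). Its slope was 1.72 (SE 0.16, adjusted p = 3.54e-07, edgeR), and its pooled counts rose 2210-fold (610.0 to 18200).

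The 2 steepest falls were lower in both 6 hpf libraries of 2013 than in any of 3 to 5 hpf, but 2 hpf 2013_42 was already as low as the 8 hpf libraries, at 103 CPM for Mle_005673 and 17.9 CPM for Mle_028632. Mle_005673 (1376 bases) held 773 ± 431 CPM at 1 hpf (SD, n = 2) and 515 ± 271 CPM at 4 hpf (SD, n = 2), was at 536 CPM in the single 5 hpf library, and stood at 50 ± 12.7 CPM at 6 hpf (SD, n = 2) and 87.0 ± 40.2 CPM at 8 hpf (SD, n = 3). Its slope was -0.55 per hour (SE 0.09, adjusted p = 5.23e-05, edgeR). Mle_028632 (1279 bases) went from 129 ± 75.6 CPM at 1 hpf (SD, n = 2) and 122 CPM at 5 hpf to 16.6 ± 14.6 CPM at 6 hpf (SD, n = 2) and 14.6 ± 5.4 CPM at 8 hpf (SD, n = 3), with a slope of -0.60 (SE 0.12, adjusted p = 0.000351, edgeR). In 7 hpf 2012_N1 these 2 transcripts stood at 1180 and 145 CPM, in the range of the early hours. In the libraries of 2012 the slopes of the 4 named transcripts had the same signs, 0.09 for Mle_016409, 0.25 for Mle_016764, -0.23 for Mle_028632 and -0.21 for Mle_005673, and none passed. With all 31 libraries both falls passed and both rises did not (adjusted p = 0.21 and 0.122, edgeR).

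**Figure D2:**
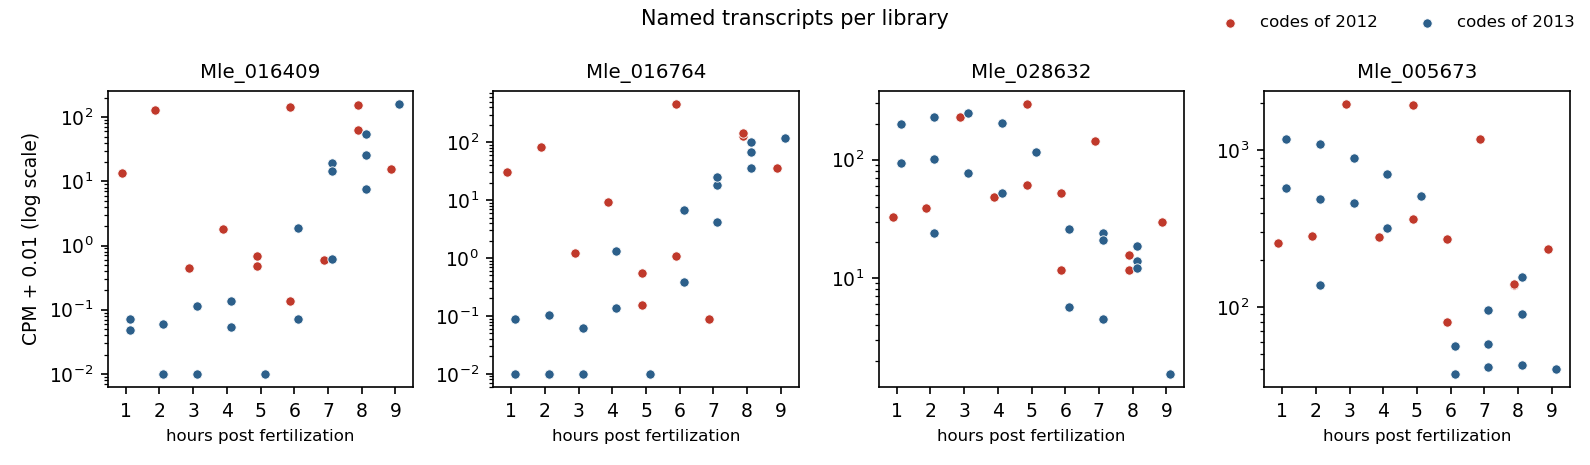
CPM plus 0.01 of the 4 named transcripts (vertical axis, log scale, TMM factors of all 31 libraries) against hours post fertilization, 1 point per library, with red for codes of 2012 and blue for codes of 2013. In the libraries of 2013 Mle_016409 and Mle_016764 climb after 5 hpf and Mle_028632 and Mle_005673 lie lower at 6 hpf than at 3 to 5 hpf, with 2013_42 at 2 hpf low as well, while 2012_N6 at 2 hpf holds 132 and 83.4 CPM of the first 2.

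As a group, the rising transcripts took 1.82 ± 0.219% of counts at 1 hpf (SD, n = 2), 3.78 ± 2.02% at 4 hpf (SD, n = 2), 7.2 ± 2.74% at 6 hpf (SD, n = 2) and 11 ± 3.16% at 8 hpf (SD, n = 3) in the libraries of 2013. The falling ones took 33.6 ± 3.04% at 1 hpf (SD, n = 2), 30.7 ± 7.51% at 2 hpf (SD, n = 3), where 2013_42 was already at 22%, and 32.8 ± 1.27% at 4 hpf (SD, n = 2), then 18.8 ± 2.97% at 6 hpf (SD, n = 2) and 22.4 ± 2.8% at 8 hpf (SD, n = 3). Of the rising transcripts 6560 (68.0%) had their highest mean at 9 hpf, where there was 1 library of 2013, and 1709 (17.7%) at 8 hpf. The falling ones were highest at 1 hpf (1137, 35.9%), 2 hpf (262, 8.27%), 3 hpf (886, 28%), 4 hpf (101, 3.19%) or 5 hpf (781, 24.7%), and 1 of them at 6 hpf or later. Because the same libraries chose these sets, the timing was read again in libraries not used to choose them. Sets called without code series 2013_2 were followed in the 8 libraries of that series, 1 per hour. There the median change of the 649 falling transcripts from 1 hpf, on the log2(CPM + 1) scale, was -0.09 at 5 hpf, -0.72 at 6 hpf and -0.84 at 8 hpf. The 7223 rising ones changed by a median of 0.12 at 5 hpf, 0.21 at 6 hpf, 0.17 at 7 hpf and 0.52 at 8 hpf. The 13888 other transcripts changed by 0.12 at 5 hpf, as much as the rising ones, and by 0.00 at 6 hpf, -0.02 at 7 hpf and 0.06 at 8 hpf. Code series 2012_N, also not used to choose the sets, did not repeat this course. After subtraction of the shared counts the 649 falling transcripts changed there by a median of 0.36 at 5 hpf, -0.09 at 6 hpf, 0.22 at 7 hpf and -0.46 at 8 hpf, with 1 library per hour.

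**Figure D3:**
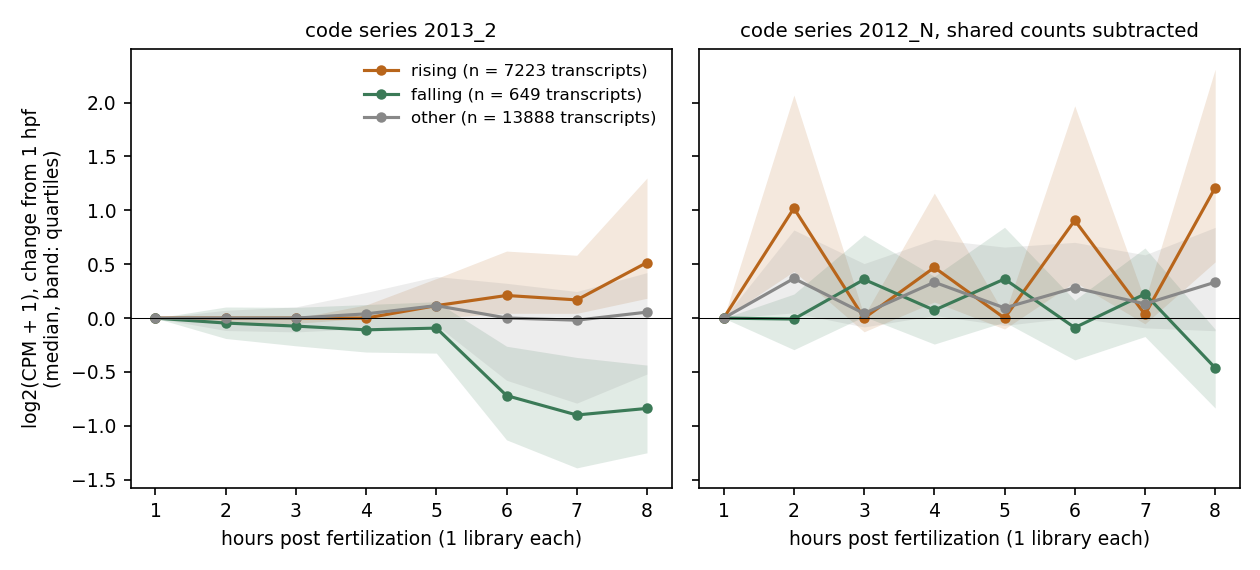
Median change from 1 hpf in log2(CPM + 1) (vertical axis) against hours post fertilization for transcripts called rising, falling or neither without code series 2013_2, with bands from the lower to the upper quartile of transcripts and 1 library per hour. In code series 2013_2 (left) the falling set is at -0.09 at 5 hpf and -0.72 at 6 hpf; in code series 2012_N after subtraction of shared counts (right) the rising set alternates, at 1.02 at 2 hpf, 0 at 3 hpf and 0.91 at 6 hpf, and the falling set is at 0.36 at 5 hpf, -0.09 at 6 hpf and 0.22 at 7 hpf.

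The change was lopsided in kind. In the libraries of 2013, 293 transcripts were under 1 CPM in both 1 hpf libraries and at 10 CPM or more in all 3 of 8 hpf, and 0 went the opposite way. Of these 293, 264 had a rising slope, which their selection on the same libraries made nearly certain. Only 1 had no count at all at 1 hpf, and the median of the set there was 0.163 CPM. The number at 1 CPM or more in every library of an hour was 6 at 2 hpf (n = 3), 33 at 3 hpf (n = 2), 157 at 4 hpf (n = 2), 223 in the single 5 hpf library, 267 at 6 hpf (n = 2) and 287 at 7 hpf (n = 3). Libraries of 1 hour differed: 2 hpf 2013_32 had 180 of them at that level, while 2013_22 and 2013_42 had 14 and 17. At 3 hpf, 2013_33 had 241 and 2013_23 had 34. Among libraries of 2012, 1 hpf 2012_N7 and 2 hpf 2012_N6 each had all 293, and 2012_N7 had 104 of them after subtraction of the 9 hpf column. The other larger column, 4 hpf 2012_N4, had 292 as deposited and all 293 after subtraction of the 5 hpf column.

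**Figure D4:**
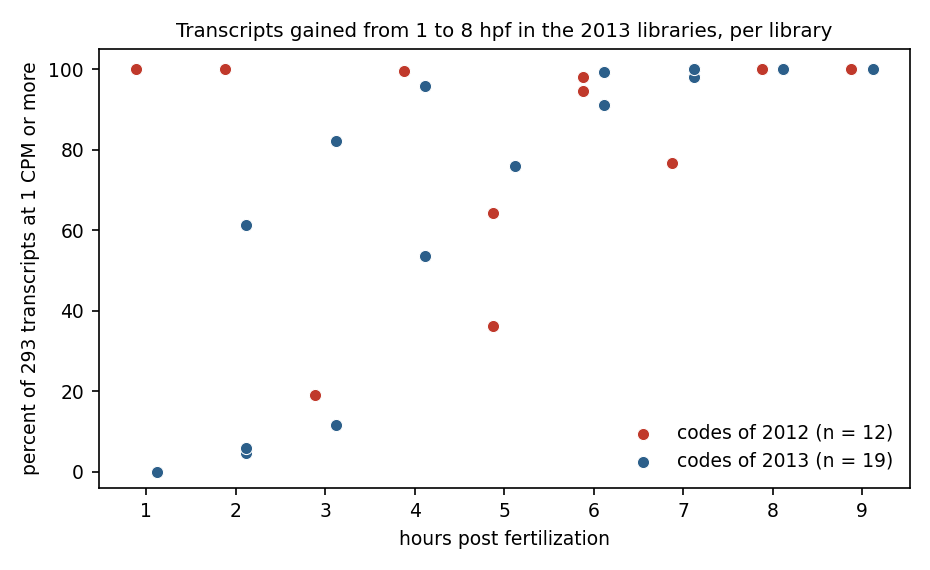
Share of the 293 transcripts that were at 1 CPM or more (vertical axis, percent) against hours post fertilization, 1 point per library, with red for codes of 2012 and blue for codes of 2013. The set was chosen on the 1 and 8 hpf libraries of 2013, so the blue points there are fixed at 0% and 100%; in between the lowest blue point is 4.78% at 2 hpf and 98.0% at 7 hpf, and 2012_N7 at 1 hpf lies at 100% (35.5% after subtraction of the 9 hpf column).

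From one hour to the next, edgeR called 0 of 23140 transcripts at each of the 8 steps over all 31 libraries. An unadjusted p under 0.05 was found for 164 transcripts from 1 to 2 hpf, 2525 from 2 to 3, 604 from 3 to 4, 354 from 4 to 5, 6135 from 5 to 6, 1639 from 6 to 7, 2122 from 7 to 8 and 81 from 8 to 9 hpf. From 1 to 2, 3 to 4, 4 to 5 and 8 to 9 hpf this was less than a share of 0.05 of those tested. Chance alone would give about that share. The 0 calls therefore do not show that levels stayed the same. DESeq2 called transcripts at every step, and by far the most from 5 to 6 hpf, 2602 higher and 329 lower. It called 2 from 1 to 2 hpf, 82 from 2 to 3, 36 from 3 to 4, 14 from 4 to 5, 32 from 6 to 7, 12 from 7 to 8 and 1 from 8 to 9 hpf. The limma test on RPKM per library called 39 from 5 to 6 hpf, 3 from 7 to 8 hpf and 0 at the other 6 steps, and on the deposited RPKM it called 0 at all 8. Within the libraries of 2012 edgeR called 51 transcripts from 5 to 6 hpf, all higher at 6 hpf, and 0 at the other steps, with between 92 and 5952 at an unadjusted p under 0.05. One of the 2 libraries of 6 hpf there is 2012_N2, which held 236 transcripts at least 10 times above every other library. None of the 51 was among these 236, and all 51 were higher in both 6 hpf libraries of 2012 than in either of 5 hpf (median 22.5 CPM in 2012_23 and 29.1 CPM in 2012_N2, against 0.822 and 0.511 CPM). The latter follows nearly from their selection, since the same libraries gave the calls. Each of those other steps has at least 1 hour with a single library of 2012, assumed to vary like the other hours, and the libraries of 1 and 4 hpf are the larger overlapping columns. Within those of 2013 it called 0 at each step, with between 49 and 1691 at an unadjusted p under 0.05. No transcript is named for the steps, since none met the rule.

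Over all 9 hours the F test called 172 of 23140 transcripts, with an unadjusted p under 0.05 for 5816. This list leaned on 1 library. Of the 172, 106 had their highest level in 6 hpf 2012_N2, and 87 were at least 10 times higher there than in any other library. Among the 5 smallest p-values were Mle_000409 (1195 bases, adjusted p = 0.000456, edgeR), Mle_019122 (2260 bases, adjusted p = 0.00132, edgeR) and Mle_013184 (859 bases, adjusted p = 0.000456, edgeR). They stood at 146, 153 and 50.7 CPM in 6 hpf 2012_N2. At 8 hpf they had means of 0.0908, 0.0846 and 0.00215 CPM (n = 5), and at 1 hpf means of 0.0783, 0.0309 and 0.00343 CPM (n = 3). Without 2012_N2 the F test called 1 transcript, and the adjusted p of Mle_000409 and Mle_019122 became 0.16 and 0.436 (edgeR). Without 2 hpf 2012_N6 it called 6752, without 1 hpf 2012_N7 3070 and without 7 hpf 2012_N1 1365. Without any other single library it called between 57 and 440, the highest without 9 hpf 2012_37. With library totals alone the F test called 74, and with the start of the code as a replicate block 2. DESeq2 called 4964, and within the 19 libraries of 2013 edgeR called 1802 of 21255.

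Between code years, with the hour in the model, 1411 of 23140 transcripts differed, 114 higher and 1297 lower in the libraries of 2013. The difference was therefore mostly in one direction. Every hour held both years, and the count stayed above 0 whichever library was left out, between 417 and 2208. It was 417 without 2 hpf 2012_N6, 585 without 6 hpf 2012_N2, 699 without 1 hpf 2012_N7, 802 without 8 hpf 2012_N8B and 832 without 6 hpf 2013_26. It was 2174 without 7 hpf 2012_N1 and 2208 without 9 hpf 2013_49. DESeq2 called 3491. The interaction term of edgeR for the change from 1 to 8 hpf called 0 of 23140 transcripts (2958 at an unadjusted p under 0.05), but rests on 2012_N7 as the only 1 hpf library of 2012 and decides nothing. The closest library by rank correlation across transcripts shared the hour for 2 of 31 libraries and the code series for 22 of 31. The median correlation did not separate these kinds of pair: it was 0.883 for 76 pairs of 1 code series and different hours and 0.881 for 41 pairs of 1 hour and different code series, and 0.873 and 0.881 after subtraction of the shared counts. For the 348 pairs that shared neither it was 0.860, and 0.858 after subtraction. Pairs of 1 code series lie from 1 to several hours apart, so these medians do not weigh the hour against the series.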

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

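The tests of both overlapping pairs of columns, of the slopes and of the difference in slope between code years were chosen only after the results were seen, while those of 2 hpf 2012_N6 and of the other splits of the libraries were written before their results were seen. Across 68 sets of 4 or 5 libraries of 1 hour, 20 values lay far from the rest of their set, where chance gives about 1 in 20 sets. That rate is no yardstick here, since the sets share libraries, some transcripts were named because of 6 hpf 2012_N2, and some values are 1 or 2 counts against 0. Most came from 3 libraries of 1 code series, 2012_N.

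The library 2 hpf 2012_N6 lay apart from the other 3 libraries of its hour. Its first component score was 91.2 (the nearest other -69.5), and rising transcripts took 12% of its counts (nearest 2.66%). Its CPM was 132 for Mle_016409 (nearest 0.0496), 83.4 for Mle_016764, 65.7 for Mle_005099 and 13 for Mle_005806, each the highest of its hour. It was also highest for Mle_000409 (0.0227 CPM) and Mle_013184 (0.0113 CPM), which had 0 counts in the other 3. The library 6 hpf 2012_N2 was highest of its hour for Mle_000409 (146 CPM), Mle_019122 (153 CPM), Mle_013184 (50.7 CPM), Mle_016409 (144 CPM) and Mle_016764 (456 CPM). In 7 hpf 2012_N1 the falling transcripts took 35.8% of counts (nearest 19.7%), with 1180 CPM for Mle_005673 and 145 CPM for Mle_028632. The remaining 4 values were Mle_000409 in 7 hpf 2013_17 (0.0436 CPM), Mle_019122 in 7 hpf 2013_27 (0.0334 CPM), Mle_013184 in 8 hpf 2012_N8B (0.0108 CPM) and Mle_005099 in 7 hpf 2013_47 (7.2 CPM). The slopes over the hours differed between code years for 1668 transcripts, tested by an interaction term, and for 252 after subtraction of the shared counts.

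The first pattern weighed was that 1 hpf 2012_N7 is nowhere below 9 hpf 2012_37. The same RNA sequenced under both labels was argued against: binomial draws at the ratio of the totals would put 4276 transcripts below (SD 56.8) and 0 were. Whether embryos of 1 hpf carry the transcripts of 9 hpf was not decided. The highest rank correlation of a 1 hpf library of 2013 with a 9 hpf library was 0.84. Libraries of the same hour would have passed the bound against this explanation too. The 1 hpf libraries 2013_21 and 2013_41 correlated at 0.885, and the 9 hpf libraries 2012_37 and 2013_49 at 0.897. A column that is the sum of the 9 hpf column and further reads would leave late transcripts nearly equal in both. This was read in the 2921 transcripts under 1 CPM in both 1 hpf libraries of 2013 and with at least 100 counts in the 9 hpf column. In 1 hpf 2012_N7 they exceeded the 9 hpf column by a median of 0.954%, against 19.5% for the totals. A candidate explanation is therefore that reads of the 9 hpf library were added to this column. No biological explanation beyond the hour was tested.

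The second pattern was that 4 hpf 2012_N4 is nowhere below 5 hpf 2012_14. Like profiles of neighbouring hours were argued against, since binomial draws would put 3101 transcripts below (SD 48.4) and 0 were. A sum of columns may apply here as well, but was not tested for this pair.

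The third pattern was the place of 2 hpf 2012_N6 among the late libraries. Greater depth was weighed by thinning, which did not decide it by the margin set beforehand. Thinned to 20733492 counts its score of rising minus falling transcripts was -2.72 (SD 0.0246 over 20 draws), as before thinning, above the -5.84 to -4.24 of the 2 hpf libraries of 2013. The margin set beforehand, more than the width of that range, was not met. At equal depth the score nevertheless stayed above every 2 hpf library of 2013. Thinning leaves shares of counts the same on average, so a nearly unchanged score was fixed in advance and decides nothing. By the same property depth alone would not give the larger share of rising transcripts. A late library under the 2 hpf label and early and late reads in one column cannot be told apart. Transcripts that fell at least 8-fold in the libraries of 2013, only 5, kept a median share of 0.46 of their early level, above the 0.0621 to 0.145 of the 8 and 9 hpf libraries of 2013. Those that rose at least 8-fold reached 1.18 of their 8 hpf level. The bound written beforehand would have excluded a late library, but it was judged wrong after the result was seen. The library 6 hpf 2012_N2 kept 0.472 and reached 0.885, and 9 hpf 2012_37 kept 0.378 and reached 0.871. The 8 hpf libraries of 2012 kept 0.234 and 0.238, and the 5 transcripts were chosen on the 8 hpf libraries of 2013. Biological variation between spawnings stays open and untested. The labels of the other 2012_N libraries, 7 hpf 2012_N1 among them, were not tested. The relations with the hour and the slopes in codes of 2012, and the 1668 differences in slope between code years, hold only for the hours as labelled.

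Other splits of the libraries were counted for each comparison. For 1 to 8 hpf 1 of 56 splits, the real one, gave as many calls (1, highest other 0). Nothing rests on this count, since the single call ended under RLE factors, library totals alone and limma and without any one of 5 libraries. After subtraction of shared counts it was again 1 of 56 (8911, highest other 0). For code years it was 1 of 60 (1411, highest other 0), and for the slopes 1 of 100 permutations of the hours (12811, highest other 311). No other split or permutation drawn reached these 3 counts. Splits and permutations treat libraries as exchangeable, but deviations from the hour's mean were correlated within code series (median 0.41 in 2013_2). Chance was therefore not excluded. At the 7 hourly steps from 1 to 8 hpf the real count was 0, below which no split can fall, so the count of splits tests nothing there: 35 of 35 from 1 to 2 hpf (highest other 10885), 35 of 35 from 2 to 3 (5584), 35 of 35 from 5 to 6 (0), 35 of 35 from 6 to 7 (0) and 100 of 100 from 7 to 8 hpf (203). From 3 to 4 and from 4 to 5 hpf the 10 splits are too few for a share under 0.05 (real 0, highest other 0 in both). The splits of the 1 and 2 hpf and of the 2 and 3 hpf libraries with many calls point to a structure of the samples other than the hour.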

How the results depend on the processing

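Subtraction of shared counts, leaving out the larger columns, leaving out single libraries of other hours for 1 to 8 hpf, limma on RPKM per library, the slope and all alternatives to the slope and to the count within 2013 were chosen only after the results were seen. The cause of the changes below was not tested unless stated.

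At the hourly steps edgeR gave 0 under RLE factors, library totals, no filter, the year term and the block. DESeq2 called 2, 82, 36, 14, 2931, 32, 12 and 1 from 1 to 2 through 8 to 9 hpf. From 1 to 2 hpf subtraction gave 10, subtraction with the block 7, and leaving out both larger columns 1, also without 2 hpf 2012_N6 (1). From 5 to 6 hpf limma on RPKM per library gave 39 and codes of 2012 alone 51, and from 7 to 8 hpf limma gave 3. Leaving out each library gave 0 to 2 from 1 to 2 hpf and 0 at the other steps.

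From 1 to 8 hpf (1 call) RLE factors, library totals, the 2 hours alone, codes of 2012 alone and all 3 limma settings gave 0, the block 41, DESeq2 28, no 9 hpf libraries 12, the year term 2 and codes of 2013 alone 3127. Subtraction gave 8911, with the block 10200, leaving out both columns 4389 and also 2012_N6 9815. Leaving out each library gave 0 to 5688, and among those of neither hour 1 to 596.

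For the F test (172) library totals gave 74, the block 2, DESeq2 4964, a linear term 6056, limma on RPKM per library 1978, on deposited RPKM 3 (pseudocount 1) and 43 (0.1), codes of 2013 alone 1802, of 2012 alone 7 and the year term 310. Subtraction gave 3221, with the block 1423, leaving out both columns 1818 and also 2012_N6 10696. Leaving out each library gave 1 to 6752. RLE factors and no filter stayed within 1.5 times.

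For code years (1411) DESeq2 gave 3491, and leaving out each library 417 to 2208. RLE factors, totals and no filter stayed within 1.5 times.

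Within 2013, from 1 to 8 hpf (3127), the block gave 9348, DESeq2 7211, the 2 hours alone 6433 and no code series 2013_2 0. Leaving out each library gave 0 to 5914. For the slope (12811) limma gave 6542, no series 2013_2 7872, and codes of 2012 alone 0 and with subtraction 0. All 31 libraries gave 6056, of which 2527 rose and 3529 fell, against 9643 and 3168 within 2013. Leaving out each library gave 10802 to 13528. No transcript was called in opposite directions by the slope and the 8 settings compared with it.

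The relations with the hour passed in 2013 under every alternative run (r 0.88 to 0.911 for the component and 0.796 to 0.877 for the number of transcripts; leaving out 1 library, 0.891 to 0.911 and 0.821 to 0.877). In 2012 they passed without 2012_N7 and 2012_N6 (r = 0.716 and 0.699), but not without 2012_N7 and 2012_37, equally far from the median hour (0.355 and 0.291), nor when each library was left out (0.132 to 0.434 and 0.0988 to 0.452).

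The start of the code was tried as a replicate block, since like codes recur between hours. Deviations from the hour's mean were to correlate above 0.1 in every pair of a series, which was met in 2013_1 (0.76), 2012_1 (0.26) and 2013_3 (lowest 0.22) but not in the 3 larger series: the lowest was -0.43 in 2012_N, -0.37 in 2013_4 and 0.098 in 2013_2 (27 of 28 pairs above). The pairing was not used for the reported counts. The 9 named results with a fold change or slope kept their direction in every alternative run. In simulated data, without overlapping columns or libraries that lay apart, 36% of 4-fold changes from 1 to 8 hpf were recovered. Changes of that size were thus often missed even there, and the share missed in the deposited columns is unknown.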

Other observations

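The comparisons of single-library transcripts and of the code series below were chosen only after the results were seen, as was the length test of the slopes, while that of 1 to 8 hpf was written before its result was seen.

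In 6 hpf 2012_N2, 236 transcripts stood at 10 CPM or more and at least 10 times above every other library, together 1.98% of its counts. Each of the other 30 libraries had 0 such transcripts.

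Along code series 2012_N, after subtraction of shared counts, the transcripts called rising without series 2013_2 alternated with the hour. Their median change from 1 hpf in log2(CPM + 1) was 1.02 at 2 hpf, 0 at 3 hpf, 0.47 at 4 hpf, 0 at 5 hpf, 0.91 at 6 hpf, 0.03 at 7 hpf and 1.21 at 8 hpf, with 1 library each. Whether the hours of these codes are right was not tested.

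The hypothesis that rising transcripts from 1 to 8 hpf in the libraries of 2013 are shorter than falling ones was tested at matched mean CPM, in 10 bins. The rising ones were longer, by 0.81 on the log2 scale (permutation p = 1e-04, two-sided, the smallest that 10000 resamples can give), so the hypothesis was not borne out for these lists, which end when any 1 library of either hour is left out. Unmatched medians were 1807 and 1759 bases. For the slopes the unmatched medians pointed the other way, 1350 bases for rising and 1906 for falling transcripts, while at matched mean CPM the rising ones were again longer, by 0.60 (permutation p = 1e-04, the smallest possible). Transcripts are not independent replicates.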
